A study of Homo sapiens and Pan troglodytes with 76 samples.

How the data were processed

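The series held 2 microarray experiments on Illumina BeadArrays, 76 arrays in all. The first measured total RNA of SH-SY5Y human neuroblastoma cells that carried an empty vector (control), human FOXP2 (humanFOXP2) or chimpanzee FOXP2 (chimpFOXP2). It had 3 lines per genotype, numbered 1, 6 and 7 in every genotype, and 4 cultures per line (36 arrays). The second measured total RNA of the caudate nucleus, frontal pole and hippocampus of 8 humans and 7 chimpanzees (40 arrays). Groups, lines and individuals were taken from the labels. Of the chimpanzee identifiers 2 are nearly alike and may be 1 animal; they were kept apart, and taken as 1 they gave 5887, 5172 and 5654 calls for caudate, frontal pole and hippocampus and 325 for species by region. The 7 brain arrays that the submitters marked as outliers were left out, which left 33: 6 human and 5 chimpanzee for caudate, 4 and 6 for frontal pole, 6 and 6 for hippocampus.

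The deposited tables of non-normalized values hold log2 signals, and so do the deposited value tables, which the authors had normalized between arrays. Column medians of the non-normalized tables spread from 6.85 to 8.98 (cells) and from 6.68 to 9.06 (brain), those of the value tables from 8.09 to 8.12 and from 7.19 to 7.23. Against quantile-normalized signals, the value tables differed probe by probe by amounts shared within sets of arrays: 3 sets in cells, which are the line numbers, and 5 in brain. The software and settings behind the value tables are not given in the sources used here. The non-normalized tables were analysed because they hold all probes: 20589 for cells, all of them also in the value table, and 24526 for brain, of which the value table keeps 15221 (62.1%). The rule by which probes were kept is not given in the sources used here. Of the probes, 18332 (cells) and 13639 (brain) had 1 gene symbol and 2257 and 10887 had none, and every brain probe with a symbol is one that the value table keeps. Symbols were matched through Entrez numbers (18315 and 13626 probes). The 7 columns of the brain value table that belong to arrays marked as outliers were not used, because each is an exact copy of another array's column (7 pairs, 3 of them across species, none in the non-normalized table).

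Work was done in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Log2 signals were returned to the linear scale, corrected for background by normexp with an offset of 50, quantile normalized within each experiment and put on the log2 scale again. This was the fallback written in the design, since the tables used hold no detection p. The planned filter on detection p had to be replaced for the same reason. The background of each array was read from its own signals as the mode of their density (kernel bandwidth of 0.05 on the log2 scale) with a spread from the values below the mode. A probe counted as above background beyond the signal that a share of 0.01 of a normal background would exceed, and was tested if this held on at least 4 arrays: 12544 probes for cells and 15516 for brain. This replacement was chosen after the signals and the counts without a filter had been seen, and after a first version that passed nearly all probes had been dropped. Signal over background limits the precision for dim transcripts. The standard error (SE) printed beside a change takes the spread between lines or individuals from 1 correlation shared by all probes. For a probe whose lines or individuals differ more than that, the SE and the p value are too small.

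Linear models were fitted with limma to all 36 cell arrays, with genotype as a fixed term, and to the 33 brain arrays, with the 6 groups of species and region as fixed terms. Cultures of 1 line, and regions of 1 individual, are not independent, so line within genotype and individual were random blocks with a consensus correlation (0.67 for cells, 0.29 for brain). Moderated tests were two-sided, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Counts are in probes. Moderated F-tests asked whether the 3 regions differed within a species and whether the species difference changed with the region. Differences are log2 differences of the model, which need not equal the difference of group means. Means are given ± SD over line means (n = 3 lines) or over arrays. Where a probe was above background on fewer arrays of a group than not, the fold is given as "at least", with each signal of that group raised to at least the dimmest signal above background on its array. Where this held for both groups no fold is given. This rule was set after the data were seen.

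The line numbers recur in every genotype, as the titles give them, but the labels do not say that lines of 1 number share anything. Pairing was therefore checked on the signals. Over probes centred within genotype, lines of the same number correlated in all 9 pairs of genotypes and numbers (r = 0.68 to 0.94) and lines of different numbers did not correlate positively (18 pairs, r = −0.77 to 0.00382; centring makes these negative). The numbers thus pair the lines in their signals, and the planned fit with the line number as a block is given beside the fit without it (correlation 0.18 after the block). Whether lines of 1 number share a cell origin or only an array run cannot be told from the signals. Gene names and lists in cells are described from the blocked fit. The numbers in the titles of the brain arrays do not pair them across species.

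Each fit was tested on simulated data in which 200 probes were changed by log2 1 or 2. For humanFOXP2 vs control (12544 probes) the fit without the block recovered 94% and 100% of them (216 calls, 10.2% of them unchanged probes) and the blocked fit 100% and 100% (231 calls, 13.4%). For human vs chimpanzee caudate (15516 probes) 91% and 99% were recovered (202 calls, 5.94%). In the simulated data unchanged probes thus made up a larger share of the calls than the threshold aims at, most of all in cells. The simulation gave every probe the same correlation and no effect particular to a line. It therefore does not give the share of unchanged probes among the calls of the real data.

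The lists of genes, the named-gene rule, the models and most alternatives were fixed before the data were examined. In each pairwise comparison the rule names the 8 genes with the largest rise and the 8 with the largest fall. They must be called, carry a symbol that is not a clone name, lie outside the Y chromosome and have groups that do not overlap. In cells this means that every line mean of one genotype lies above every line mean of the other. In brain 1 array of each group may lie in the other's range. Groups of 3 lines and 3 lines that are not paired do not overlap in 10% of cases by chance. The lines here are paired by number, and 1.46% to 1.73% of all probes did not overlap. FOXP2 is named throughout, with up to 4 members per described list, 6 genes per F-test and 10 genes of the overlap. Of the genes that the rule gives for chimpFOXP2 vs control 1 is not described, which fell by more than those given. A gene named outside this rule is said to have been chosen after its values were seen.

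Lists were tested with camera in limma on data whitened for the random block, 1 probe per gene (the one with the brightest mean signal). The inter-gene correlation was preset to 0.01 and, as a second test, estimated. P values were adjusted over the lists of a comparison. Members were also adjusted over their list alone. In cells 24 lists were tested: FOXP family, reported FOXP2 targets, sympathoadrenal transcription factors, catecholamine synthesis and transport, secretory granule and neuropeptides, mesenchymal (S-type) markers, neurite cytoskeleton, synaptic vesicle, axon guidance, Wnt signalling, Notch signalling, retinoic acid response, extracellular matrix and cartilage, cell cycle, interferon response, MHC class I, unfolded protein and amino acid response, cholesterol synthesis, hypoxia and glycolysis, p53 response, cancer-testis antigens, ribosomal proteins, oxidative phosphorylation and proteasome. In brain 26 were tested: synaptic vesicle, axon guidance, interferon response, MHC class I, unfolded protein and amino acid response, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, proteasome, the markers of neurons in general, glutamatergic neurons, GABAergic interneurons, medium spiny neurons, hippocampus, cortical layers, astrocytes, oligodendrocytes, their precursors, microglia, endothelium and ependyma, and blood cell genes, immediate early genes, heat shock proteins, acute-phase and hypoxia response, and glutamate and GABA receptors. The FOXP family and the reported FOXP2 targets had fewer than 2 measured members there and were not tested. Lists of each region against the other 2 were added after the data were seen.

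The overlap between the 2 experiments was tested by gene symbol with Fisher's exact test, and directions with an exact binomial test, both two-sided. Alternatives changed the background correction, the normalization between arrays, the source of values, the probe filter, the treatment of lines and individuals, the arrays and the probes. Blocks for the sets of arrays that the value table treats alike were inferred from probes with a mean signal of at least 8, with the number of sets in brain chosen after looking. A block for the beadchip was not run, because the files name none, and a subset of probes that match chimpanzee transcripts was not run, because probe sequences were not used here.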

Results

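The arrays covered SH-SY5Y neuroblastoma cells with an empty vector, human FOXP2 or chimpanzee FOXP2 (3 lines and 12 arrays per genotype) and 3 brain regions of humans and chimpanzees (33 arrays). In the cells the share of probes above background had a median of 54.5% in control, 54.3% in humanFOXP2 and 54.9% in chimpFOXP2 arrays, with single arrays from 47.2% to 59.5%. Line 1 arrays were dimmer in every genotype (median deposited log2 signal 6.85 to 7.43) than those of line 6 (8.22 to 8.97) and line 7 (8.34 to 8.98). In the brain the median share was 50.8% (caudate, n = 5), 51.7% (frontal pole, n = 6) and 52.3% (hippocampus, n = 6) in chimpanzee and 47.6% (n = 6), 46.8% (n = 4) and 47.9% (n = 6) in human. Human frontal pole arrays were the most uneven, from 32.0% to 58.4%, with deposited medians from 6.98 to 9.06.

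The first question was how much FOXP2 transcript the lines made. FOXP2, a forkhead transcription factor in which variants cause a speech and language disorder, was above background on none of the 12 control arrays and on all 12 arrays of either FOXP2 genotype. Its log2 signal was 6.99 ± 0.06 in control, 11.16 ± 0.32 in humanFOXP2 and 10.61 ± 0.88 in chimpFOXP2 (mean ± SD, n = 3 lines). FOXP2 thus rose by log2 4.17 (SE 0.23, at least 11.2-fold, adjusted p = 1.14e-15) with human FOXP2 and by 3.62 (SE 0.23, at least 7.65-fold, adjusted p = 1.23e-13) with chimpanzee FOXP2, and with the line number as a block the adjusted p was 8.80e-21 and 1.04e-18. ChimpFOXP2 lines 1, 6 and 7 stood at 10.01, 10.21 and 11.62, humanFOXP2 lines at 11.32, 10.79 and 11.38. The difference between the 2 FOXP2 genotypes was log2 0.55 (adjusted p = 1.00, blocked 0.0753), and without chimpFOXP2 line 7 it was 1.05 (adjusted p = 0.00582). The call of FOXP2 against control was lost when the 4 cultures were averaged first (chimpFOXP2, adjusted p = 0.146). The call was also lost on line means with the block (0.159, and 0.0628 for humanFOXP2). In these fits the differences stayed at log2 3.62 and 4.17. FOXP1, FOXP3 and FOXP4 were not called.

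**Figure D1:**
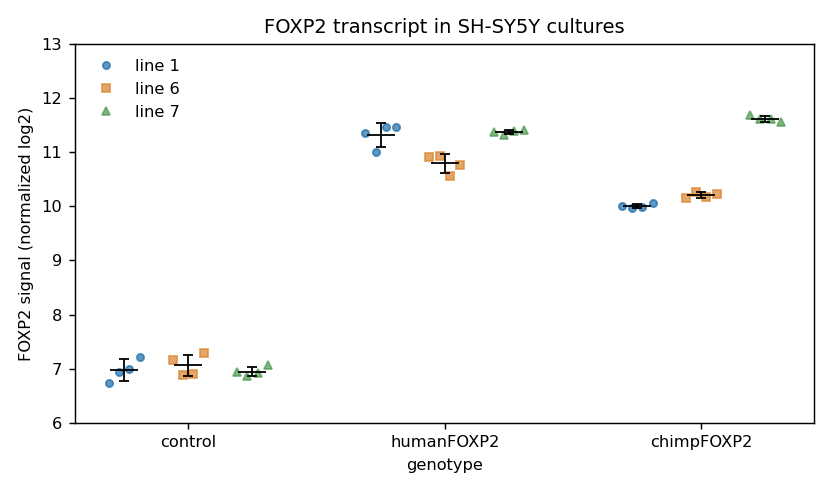
FOXP2 log2 signal of each SH-SY5Y culture (points) by genotype and line number. Bars are line means and error bars the SD of 4 cultures; control lines lie at 6.95 to 7.06, humanFOXP2 lines at 10.79 to 11.38 and chimpFOXP2 lines at 10.01 to 11.62.

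The next question was which other genes changed with human FOXP2. Without the block FOXP2 was the only probe called by limma (1 of 12544, with 10 at an unadjusted p under 0.05), and with it 8 probes were called, 6 up and 2 down (386 at an unadjusted p under 0.05). A blocked fit of these 2 genotypes alone called 230. The blocked fit takes the 4 cultures of a line as replicates with a shared correlation; on line means with the block limma called 0 probes (171 at an unadjusted p under 0.05). STX3, a syntaxin of membrane fusion, rose from 8.85 ± 0.15 to 9.19 ± 0.15 (n = 3 lines, 1.27-fold, SE 0.05 on the log2 scale, adjusted p = 6.92e-04). SIX5, a homeobox transcription factor, rose from 8.89 ± 0.04 to 9.23 ± 0.18 (1.26-fold, SE 0.06, adjusted p = 0.00861). The other 5 called genes were chosen after their values were seen, because their line means overlapped. CGNL1, a tight junction protein (1.67-fold, adjusted p = 8.77e-08), PROM1, which encodes CD133 (1.53-fold, adjusted p = 0.00133), and MRAP2, an accessory protein of melanocortin receptors (1.34-fold, adjusted p = 0.00224), rose. CBLN4, a secreted synaptic organizer (−0.68 on the log2 scale, adjusted p = 5.23e-05), and H1-2, a linker histone (−0.31, adjusted p = 0.0417), fell. Line means did not overlap for 3 of the 8 probes (37.5%, against 1.46% of all probes; 10% would hold by chance only for lines that are not paired). FOXP2, CGNL1 and CBLN4 stayed called whichever single line of 1 genotype was left out. With line 7 of every genotype left out, CBLN4, H1-2, SIX5 and STX3 were not called. Without control line 7, H1-2, PROM1, SIX5 and STX3 were not called (the adjusted p of SIX5 reached 0.886 over all lines left out), and without chimpFOXP2 line 1 the count was 46. MRAP2 was at 0.23 without control line 6, from 0.42.

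Of 24 lists, 3 rose with human FOXP2 in the blocked fit. Of the FOXP family 1 of 4 measured members rose, FOXP2 itself (adjusted p = 3.48e-07). Mesenchymal markers, which mark the substrate-adherent cell type of neuroblastoma, rose as a list, with 9 of 11 positive, a median of log2 0.08 and no member called (adjusted p = 0.00210). Adjusted over the list alone 3 of them rose, the intermediate filament VIM (0.38), LGALS1 (0.21) and EGFR (0.18). Catecholamine synthesis and transport rose with 6 of 7 positive, a median of 0.04 and no member called (adjusted p = 0.0124); the noradrenaline transporter SLC6A2 (0.32) rose when adjusted over the list alone. These 3 kept their call with an estimated correlation (adjusted p = 4.94e-04, 0.00523 and 0.0218 with an estimated correlation), under which the blocked fit called 1 list after median centring. On line means 2 lists were called, none with an estimated correlation, and on line means with the block 0. Without the block catecholamine genes were not called (adjusted p = 0.0548). Retinoic acid response and hypoxia were called there, with an adjusted p of 0.0173 and 0.0470 (blocked 0.0837 and 0.0806), and not with an estimated correlation (adjusted p = 0.0787 and 0.307 with an estimated correlation).

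Chimpanzee FOXP2 was compared with control in the same way, with genes named from the blocked fit. IGFBP3, a binding protein of insulin-like growth factors, rose from 7.99 ± 0.31 to 8.97 ± 0.38 (n = 3 lines, 1.98-fold, SE 0.14, adjusted p = 3.40e-05) and MRAP2 from 10.47 ± 0.28 to 11.25 ± 0.45 (1.72-fold, SE 0.07, adjusted p = 5.30e-09). FAM43A (1.47-fold, adjusted p = 2.96e-04), the zinc finger transcription factor SALL4 (1.43-fold, adjusted p = 0.00895) and the growth factor receptor EGFR (8.36 ± 0.06 to 8.85 ± 0.19, 1.40-fold, adjusted p = 5.02e-05) also rose. So did PHACTR2, a regulator of actin and phosphatase 1 (1.38-fold, adjusted p = 0.00113), and the dynein chain DYNC1I1 (1.32-fold, adjusted p = 0.00411). TMEM54 (−0.42 on the log2 scale, adjusted p = 0.0294), the glutathione transferase MGST1 (−0.39, 0.00227), the netrin-G1 ligand LRRC4C (−0.34, 0.0274) and ZDHHC22 (−0.30, 0.00223) fell. GAREM1 (−0.30, 0.0314), the latrophilin ADGRL2 (−0.23, 0.0367) and the citron kinase CIT (−0.22, 0.0363) fell as well. MGST1 and LRRC4C lay near background in both genotypes (4 and 3 of 12 control and 1 and 1 of 12 chimpFOXP2 arrays above it). The size of their difference is thus not measured, and its direction is uncertain.

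These calls depend on the block. Without it limma called FOXP2 alone (1 probe, 108 at an unadjusted p under 0.05), and with it 195 probes, 116 up and 79 down (1413 at an unadjusted p under 0.05). On line means with the block, where cultures are averaged first, it called 0 (607 at an unadjusted p under 0.05), the named genes included. Splits that mixed the 2 genotypes, with 1 line of each number per group, called 559, 85 and 525 probes with the block. The median-centred scale put 69.1% of the blocked calls higher, against 59.5% here, and for human FOXP2 90.9% against 75%. Line means did not overlap for 34 of the 195 (17.4%, against 1.58% of all probes), and 149 had the same direction in all 3 lines. Leaving out control line 6 gave 63 calls and ended 9 of the 16 that the naming rule gives, among them PHACTR2, DYNC1I1 and MGST1; leaving out chimpFOXP2 line 7 gave 1007 and ended none. Without chimpFOXP2 line 6, which ended 8, SALL4 was at 0.27, PHACTR2 at 0.28 and DYNC1I1 at 0.17; without control line 7, which ended 6, TMEM54 was at −0.24. FOXP2, IGFBP3, MRAP2, FAM43A, EGFR and ZDHHC22 kept their call in the blocked fit whichever single line was left out.

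Of the lists, 8 changed with chimpanzee FOXP2, with and without the block, and in the blocked fit all 8 kept the call with an estimated correlation. Under that correlation 2 lists were called after median centring with the block, 1 without it, and 0 on line means with or without the block. Cell cycle genes fell as a list (3 of 25 positive, median −0.10, adjusted p = 2.03e-07, 0.00120 with an estimated correlation), with no member called; its members included the mitotic kinase AURKB (−0.16) and cyclin CCNA2 (−0.13). Cholesterol synthesis fell (2 of 14 positive, median −0.12, adjusted p = 3.27e-04, 0.00447 with an estimated correlation), with no member called, and 4 fell when adjusted over the list alone, among them HMGCS1 (−0.18) and INSIG1 (−0.23). The p53 response rose (9 of 10 positive, median 0.13, adjusted p = 1.01e-04, 0.00404 with an estimated correlation). Its called members were the cyclin-dependent kinase inhibitor CDKN1A (0.61, SE 0.13, adjusted p = 0.00580) and the death receptor TNFRSF10B (0.21, SE 0.04, 0.00113), and 6 rose adjusted over the list alone. TNFRSF10B kept its call in all 9 fits with a line left out, CDKN1A in 7 (0.22 without chimpFOXP2 line 1; also lost without control line 1). Catecholamine genes rose (5 of 7 positive, median 0.17, adjusted p = 0.00168, 0.00447 with an estimated correlation), with GCH1, which makes the cofactor of tyrosine hydroxylase (0.37, adjusted p = 0.00429), and the vesicular transporter SLC18A1 (0.24, 0.0121) called. GCH1 kept the call in 6 of the 9 fits (0.18 without chimpFOXP2 line 6; lost also without control line 6 or 7) and SLC18A1 in 7 (0.12 without chimpFOXP2 line 1; lost also without control line 1).

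Mesenchymal markers rose with chimpanzee FOXP2 (8 of 11 positive, median 0.11, adjusted p = 0.00313, 0.00560 with an estimated correlation), with EGFR and VIM (0.46, SE 0.12, adjusted p = 0.0329) called. VIM kept the call in 4 of 9 fits with a line left out (0.15 without chimpFOXP2 line 1; lost also without line 1 or 7 of control or humanFOXP2). The interferon response rose (10 of 12 positive, median 0.05, adjusted p = 0.0138, 0.0219 with an estimated correlation), with ISG20 (0.25, adjusted p = 0.0490) called, and so did the unfolded protein and amino acid response (10 of 13 positive, median 0.07, adjusted p = 0.00876, 0.0482 with an estimated correlation), with none called and DDIT4 (0.26) risen over the list alone. ISG20 kept the call in 4 of 9 (0.11 without chimpFOXP2 line 1; lost also without line 1 or 6 of control and line 1 or 7 of humanFOXP2). The FOXP family was called up through FOXP2 (mean 0.88, median −0.03, adjusted p = 0.00433, 0.0239 with an estimated correlation). Without the block catecholamine and cholesterol genes were not called with an estimated correlation (adjusted p = 0.135 and 0.168 with an estimated correlation). Single members changed in lists that did not: the neuropeptide VIP fell 3.93-fold (−1.98, SE 0.26, adjusted p = 1.41e-05), the intermediate filament peripherin, PRPH, rose (1.07, SE 0.21, 0.00411), and the vasodilator peptide ADM fell (−0.43, 8.42e-06). VIP and ADM kept the call in all 9 fits (ADM at −0.28 without chimpFOXP2 line 6). PRPH was above background on 4 of 12 control arrays (at least 1.73-fold) and kept the call in 5 of 9, not without line 1 or 6 of control or chimpFOXP2 (0.69 without chimpFOXP2 line 6).

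The third question was whether the human and the chimpanzee protein differ in effect. LINGO1, a membrane protein that restrains axon growth and myelination, was higher with human FOXP2 (9.64 ± 0.15 against 9.18 ± 0.37, n = 3 lines, 1.38-fold, SE 0.08, adjusted p = 0.00279), and so was MGST1 (7.55 ± 0.15 against 7.13 ± 0.36, adjusted p = 0.00279). LRRC4C was called too (adjusted p = 0.0205), but MGST1 and LRRC4C lay near background (above it on 3 and 1 of 12 arrays, and on 5 and 1). No fold is given for these 2 genes, and their direction is uncertain. The angiomotin AMOT (1.22-fold, 0.0444), the chromatin protein HMGB2 (1.19-fold, 0.0476) and CIT (1.17-fold, 0.0315) were higher too. The spindle protein SPAG5 (1.12-fold, 0.0236) and ODC1, the first enzyme of polyamine synthesis (1.11-fold, 0.0462), followed. IGFBP3 was lower with human FOXP2 (8.24 ± 0.37 against 8.97 ± 0.38, −0.74, SE 0.14, adjusted p = 0.00360), as was TMEM100 (11.11 ± 0.27 against 11.76 ± 0.36, −0.65, SE 0.14, 0.0123). The neurotrophic factor NRTN (−0.33, 0.00669), the interleukin subunit IL12A (−0.29, 0.00202) and TIGAR, a p53-induced regulator of glycolysis (−0.25, 0.0186), were lower as well. Without the block limma called no probe (0 of 12544, 92 at an unadjusted p under 0.05), and with it 162, 91 higher and 71 lower (1438 at an unadjusted p under 0.05), of which 95 had the same direction in all 3 lines. On line means with the block it called 0 (636 at an unadjusted p under 0.05). Splits that mixed the 2 genotypes, with 1 line of each number per group, called 258, 288 and 286 probes with the block. Each of these was more than the real 162. Line means did not overlap for 16 of the 162 (9.88%, against 1.73% of all probes). Without humanFOXP2 line 6 there were 5 calls, and of the 13 named genes IL12A alone was left; without chimpFOXP2 line 7 there were 1189. Without chimpFOXP2 line 6 the named calls left were 2, without humanFOXP2 line 1 4. Sizes shrank with them: without chimpFOXP2 line 6 TMEM100 was at −0.25, NRTN at −0.16, HMGB2 at 0.14 and ODC1 at 0.08, without humanFOXP2 line 6 IGFBP3 at −0.35 and SPAG5 at 0.11, and without chimpFOXP2 line 1 TIGAR at −0.16.

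**Figure D2:**
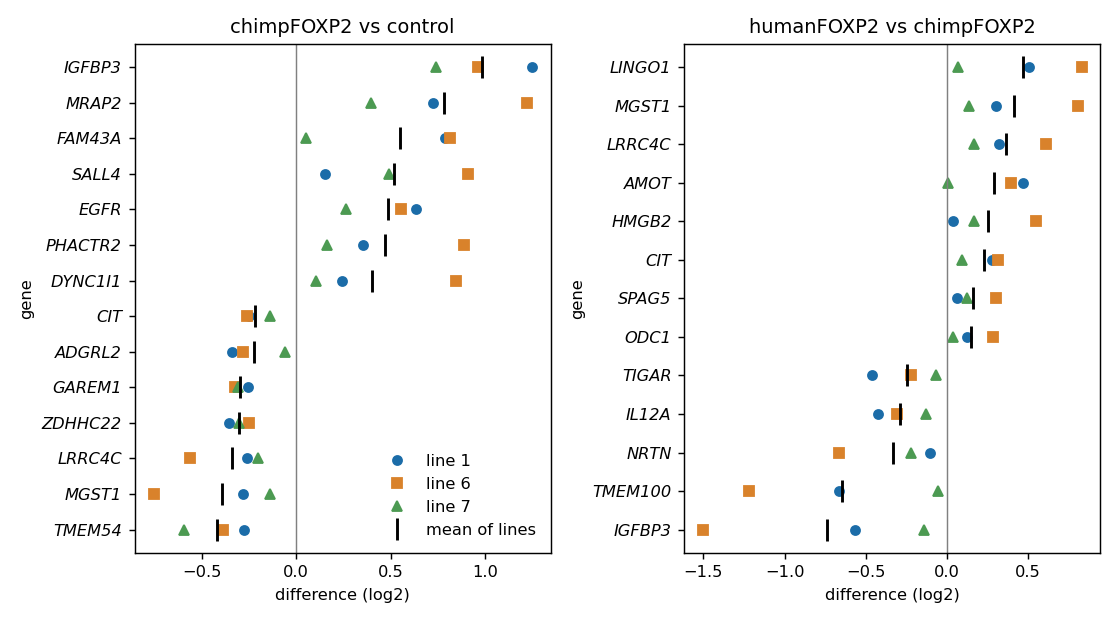
Log2 difference of each named gene in SH-SY5Y lines, chimpFOXP2 minus control (14 genes) and humanFOXP2 minus chimpFOXP2 (13 genes). Symbols mark the difference within lines 1, 6 and 7 and the black tick the mean of the 3 lines; IGFBP3 had a mean of 0.98 in the first panel and −0.74 in the second.

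Between the 2 FOXP2 genotypes 7 lists were called with the block and 3 kept the call with an estimated correlation. With that correlation 1 list was called after median centring with the block and 0 on line means with or without it. Cell cycle genes were higher with human FOXP2 (19 of 25 positive, median 0.07, no member called, adjusted p = 6.92e-04, 0.0340 with an estimated correlation). The p53 response was lower (2 of 10 positive, median −0.10, no member called, adjusted p = 0.00786, 0.0343 with an estimated correlation), with CDKN1A (−0.43) lower over the list alone. The interferon response was lower too (2 of 12 positive, median −0.12, adjusted p = 0.0126, 0.0340 with an estimated correlation), with IFIT2 (at least 1.12-fold lower, adjusted p = 0.0475) called. IFIT2 was above background on 2 of 12 humanFOXP2 arrays and kept the call in 3 of 9 fits with a line left out; it was lost without any 1 of the control lines, without chimpFOXP2 line 6 and without humanFOXP2 line 1 or 6. Calls of 4 lists were lost with an estimated correlation: cholesterol synthesis, higher (adjusted p = 0.0241, 0.0733 with an estimated correlation), hypoxia and glycolysis, higher (0.0208, 0.245), cancer-testis antigens, lower (0.0110, 0.0636), and ribosomal proteins, lower (0.0431, 0.245). Of the hypoxia list ADM (0.40, adjusted p = 2.24e-04) and PFKP (0.25, 0.0230) were called. ADM kept its call in all 9 fits (0.25 without chimpFOXP2 line 6), PFKP in 6 (0.10 without chimpFOXP2 line 1; lost also without humanFOXP2 line 1 or 6). Without the block the cholesterol and cancer-testis lists were not called (0.0661 and 0.0528), and the FOXP family and retinoic acid response were (0.0449 and 0.0365; blocked 0.123 and 0.121), neither with an estimated correlation (adjusted p = 0.154 and 0.110 with an estimated correlation). Axon guidance had 2 of 20 members called, SLIT1 (0.54, adjusted p = 0.00360) and EFNB2 (0.37, 0.0171; 0.13 without chimpFOXP2 line 6). Both lost the call without chimpFOXP2 line 6 or humanFOXP2 line 1 or 6.

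The other lists were called in no cell comparison, and their lowest blocked adjusted p was 0.110 for reported FOXP2 targets, 0.495 for sympathoadrenal transcription factors, 0.202 for secretory granule and neuropeptides, 0.483 for neurite cytoskeleton, 0.282 for synaptic vesicle, 0.123 for axon guidance and for Wnt signalling, 0.313 for Notch signalling, 0.404 for extracellular matrix and cartilage, 0.601 for MHC class I, 0.892 for oxidative phosphorylation and 0.103 for proteasome. Of the reported FOXP2 targets CNTNAP2, a neurexin family adhesion protein, stood at −0.22 with chimpanzee FOXP2 (adjusted p = 0.216, 0.0318 adjusted over the list alone) and at −0.19 with human FOXP2 (adjusted p = 1.00).

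The comparisons share arrays. Differences of humanFOXP2 and of chimpFOXP2 against control correlated at r = 0.45, against 0.50 in 20 simulated draws with shared controls and no effect, and 6 probes were called in both, all in the same direction (0 at most in the draws). With separate control lines r was 0.19 and 5 probes were shared. The chimpFOXP2 effect and the difference between the FOXP2 genotypes correlated at r = −0.70 (simulated −0.50), with 86 probes called in both in opposite directions (0 at most in the draws). With chimpFOXP2 lines split between them r was −0.55 and 3 probes were shared. Draws without an effect leave little to call, so their 0 does not measure how many shared calls the shared arrays bring. Within single lines the effects were unlike: the chimpFOXP2 difference from control correlated between lines at r = 0.01 (1 and 6), −0.31 (1 and 7) and 0.11 (6 and 7), and the humanFOXP2 difference at 0.07, 0.38 and 0.08. The difference between the FOXP2 genotypes correlated between lines at −0.07, −0.07 and −0.12.

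The brain arrays asked how human and chimpanzee regions differ. Whether the probes named below bind chimpanzee RNA as well as human RNA was not tested. In the caudate nucleus the glutathione transferase GSTM3 had a signal of 10.46 ± 0.51 in human (n = 6) and 5.90 ± 0.19 in chimpanzee (n = 5), at least 15.3-fold higher (log2 4.55, SE 0.20, adjusted p = 3.37e-19). TM2D3 (at least 13.2-fold, adjusted p = 2.47e-09), the proline dehydrogenase PRODH (at least 8.77-fold, 4.55e-14) and the splicing factor SF3A3 (at least 9.98-fold, 6.55e-22) were higher in human. So were the metallothionein MT1M (at least 9.72-fold, 8.52e-09), CSRNP3 (at least 10.5-fold, 1.96e-13), the prostaglandin D2 synthase PTGDS (13.08 ± 0.29 against 10.13 ± 0.42, 7.41-fold, 7.86e-12) and CERCAM (6.49-fold, 8.59e-08). Higher in chimpanzee were the interleukin receptor chain IL2RB (9.44 ± 0.62 against 6.30 ± 0.29, at least 6.84-fold, SE 0.19, adjusted p = 2.62e-15), the ribosomal protein RPL36 (6.10-fold, 3.25e-17), the complement factor CFD (at least 5.55-fold, 8.56e-14) and CHURC1 (5.58-fold, 1.38e-08). HLA-DRB5 (8.44 ± 0.60 against 6.22 ± 0.61, at least 3.23-fold, 1.00e-06), the transcription factor BHLHE22 (at least 3.62-fold, 1.25e-06), the orphan receptor GPR12 (4.36-fold, 2.07e-11) and RASL11B (4.20-fold, 1.76e-06) followed. The level of HLA-DRB5 in a person follows the haplotype, so its difference may depend on which people were measured. Of 15516 probes 6113 were called, 2634 higher and 3479 lower in human.

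In the frontal pole (4 human, 6 chimpanzee) GSTM3 was at least 10.9-fold higher in human (9.95 ± 0.52 against 6.04 ± 0.15, adjusted p = 1.51e-16), CSRNP3 13.7-fold (1.56e-13) and SF3A3 at least 9.44-fold (2.72e-21). TM2D3 stood at 11.07 ± 0.36 against 6.63 ± 1.47 (2.77e-09), with 1 of 6 chimpanzee arrays above background and far from the others. MT1M (at least 6.08-fold, 3.14e-07), PRODH (at least 5.85-fold, 5.31e-12), PTGDS (7.25-fold, 5.07e-11) and the zinc finger protein ZNF91 (5.60-fold, 2.97e-07) were higher too. Higher in chimpanzee were the dehydrogenase DHRS1 (10.49 ± 0.18 against 7.90 ± 0.20, 6.04-fold, SE 0.17, adjusted p = 3.70e-14), FLYWCH1 (5.75-fold, 3.28e-14), gliomedin, GLDN (4.83-fold, 2.28e-04), and CFD (4.37-fold, 5.74e-11). GSTT1 (10.17 ± 0.25 against 7.97 ± 1.53, 4.36-fold, 3.12e-04), RPL36 (4.07-fold, 1.66e-13), lipocalin 2, LCN2 (at least 3.18-fold, 4.56e-09), and CHURC1 (3.86-fold, 4.76e-06) followed. The level of GSTT1 in a person follows a common deletion, so its difference may depend on which people were measured. Of the probes 5257 were called, 2169 higher and 3088 lower in human.

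In the hippocampus (6 and 6) TM2D3 was higher in human (10.86 ± 0.37 against 6.59 ± 1.33, adjusted p = 5.69e-10), again with 1 of 6 chimpanzee arrays above background and apart. Higher in human were also GSTM3, at least 11.4-fold (3.48e-18), CSRNP3 at least 11.6-fold (2.35e-14), PRODH at least 9.04-fold (9.49e-15), SF3A3 at least 9.41-fold (1.23e-22) and MT1M at least 7.63-fold (3.19e-08). LHFPL6 (at least 4.90-fold, 1.07e-14) and the endoplasmic reticulum chaperone HSPA5 (8.78 ± 0.16 against 6.31 ± 0.16, at least 4.84-fold, SE 0.12, 6.76e-18) were higher as well. The HSPA5 probe was also above background on 0 of 5 chimpanzee caudate and 0 of 6 chimpanzee frontal pole arrays. GSTM3, SF3A3, PRODH and MT1M were likewise not above background on most chimpanzee arrays of each region. Whether these probes bind chimpanzee RNA was not tested. Higher in chimpanzee were CHURC1 (6.29-fold, adjusted p = 1.39e-09), CFD (5.36-fold, 1.58e-13), LCN2 (8.65 ± 0.10 against 6.35 ± 0.51, at least 3.66-fold, 1.09e-11) and ZCCHC12 (4.82-fold, 3.72e-06). DHRS1 (4.43-fold, 2.96e-13), NAALADL1 (at least 3.35-fold, 2.24e-17), RPL36 (4.22-fold, 5.04e-15) and FLYWCH1 (4.05-fold, 6.18e-13) were higher there too. Of the probes 5876 were called, 2534 higher and 3342 lower in human. FOXP2 was above background on at most 1 array of a group and was not tested, and FOXP1 was not called (caudate −0.17, adjusted p = 0.169; frontal pole −0.08, 0.587; hippocampus 0.16, 0.190).

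Many species differences were common to the regions: 3236 probes were called in all 3, each with the same direction (1529 higher and 1707 lower in human), out of 8609 called in any. Groups did not overlap for 67.7% of the called probes in caudate, 76.5% in frontal pole and 52.9% in hippocampus (28.3%, 29.8% and 20.4% of all probes). The direction depended on the class of probe. Among probes that the value table keeps, 23.9%, 20.5% and 23.2% of those called (3554, 3013 and 3412) were higher in human, and among those it leaves out 69.8%, 69.1% and 70.7% (2559, 2244 and 2464). With the kept probes normalized alone, which centres their differences, 1341 of 2954, 934 of 2270 and 1241 of 2745 calls were higher in human. Median centring put 34.4%, 26.7% and 32.4% of all calls higher, against 43.1%, 41.3% and 43.1% here, and moved the median difference of all probes to −0.14, −0.21 and −0.14. With the adjustment sets of the value table as a block, chosen after the data were seen, 2906, 1306 and 2210 probes were called, and 4 named genes lost their call. CERCAM in caudate kept it but went from 2.70 (SE 0.34) to 1.73 (SE 0.52, adjusted p = 0.0172), and ZNF91 in frontal pole from 2.48 (SE 0.33) to 1.58 (SE 0.41, 0.0124). BHLHE22 in caudate went from −2.13 (SE 0.31) to −0.96 (SE 0.48, adjusted p = 0.177), a smaller difference. In frontal pole GLDN went from −2.27 (SE 0.46) to −2.40 (SE 0.94, 0.120), CHURC1 from −1.95 (SE 0.30) to −1.69 (SE 0.62, 0.0892) and GSTT1 from −2.12 (SE 0.44) to −1.52 (SE 0.88, 0.322), each with an SE that grew. The arrays were of 1 type for both species, and whether each probe matches its chimpanzee transcript was not tested.

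**Figure D3:**
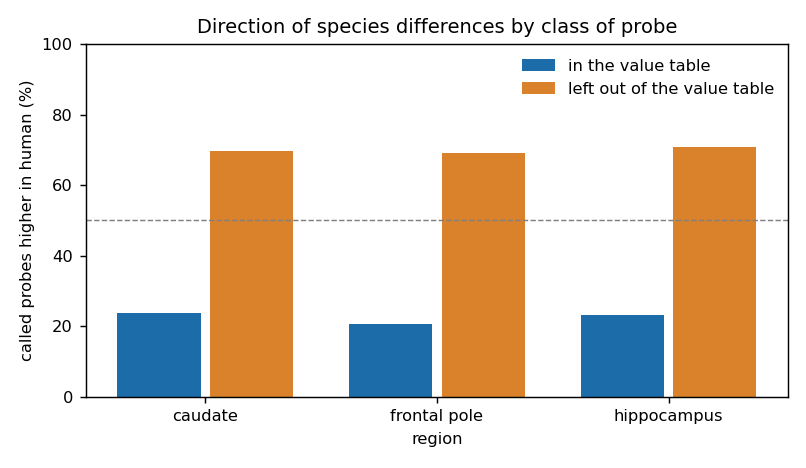
Percent of called probes that were higher in human than in chimpanzee, by region, for probes that the value table keeps and probes that it leaves out. The dashed line marks 50 percent; the bars stand at 20.5 to 23.9 for kept probes and at 69.1 to 70.7 for the others.

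As groups, few gene lists differed between the species. Oxidative phosphorylation genes were lower in human caudate (14 of 25 fell, 1 rose, median −0.41, adjusted p = 0.0333, 0.988 with an estimated correlation) and hippocampus (13 fell, 1 rose, median −0.37, 0.0456, 0.959 with an estimated correlation). In caudate the members UQCRH (−1.05, adjusted p = 1.43e-05), NDUFV1 (−1.01, 6.80e-05) and COX8A (−0.72, 5.17e-05) fell, while the ATP synthase subunit ATP5F1D rose (0.77, 7.47e-05). Proteasome genes were lower in human hippocampus (14 of 21 fell, 2 rose, median −0.47, adjusted p = 0.0384, 0.959 with an estimated correlation), among them PSMB7 (−0.74, 3.39e-06) and PSMA2 (−0.78, 1.01e-05). None of the 3 calls held over value-table probes normalized alone, where 0 lists were called in each region.

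The remaining lists were not called. In the frontal pole every list had an adjusted p of 0.992. In caudate the adjusted p was 0.0540 for proteasome, 0.0666 for GABAergic interneurons, 0.236 for medium spiny neurons, 0.407 for synaptic vesicle and microglia, 0.528 for neurons in general, astrocytes and endothelium and 0.612 for glutamate and GABA receptors. It was 0.716 there for ribosomal proteins, unfolded protein response and acute-phase and hypoxia response, 0.747 for axon guidance and cholesterol synthesis, 0.763 for oligodendrocyte precursors, 0.980 for immediate early genes and 0.996 for cortical layers. It was 0.873 for interferon response, MHC class I, heat shock proteins, blood cell genes and the markers of glutamatergic neurons, hippocampus, oligodendrocytes and ependyma. In hippocampus the other lists lay between 0.196 (GABAergic interneurons) and 0.998 (neurons in general).

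Regions differed within both species, and many probes were called in both. SLC17A7, the vesicular glutamate transporter of cortical and hippocampal neurons, was dim in caudate (6.32 ± 0.11 in human, 6.31 ± 0.19 in chimpanzee). It was bright in frontal pole (11.73 ± 0.45 and 11.50 ± 0.17) and hippocampus (11.89 ± 0.37 and 11.73 ± 0.27; adjusted p = 1.01e-25 in human and 4.64e-25 in chimpanzee). The GABA-B receptor subunit GABBR2 (3.27e-20 and 1.27e-18) was likewise lower in caudate, and so were the glycosyltransferase GALNT9 (2.10e-20 and 3.17e-14) and the syntaxin STX1A (2.81e-17 and 3.12e-13). The carbonic anhydrase CA12 was higher in caudate in both (11.16 ± 0.17 and 11.61 ± 0.33; 7.45e-19 and 8.61e-19), as were KLHL13 (7.68e-18 and 3.56e-17), DDIT4L (8.99e-14 and 5.03e-18) and the dopamine signalling protein PPP1R1B (14.08 ± 0.20 and 14.18 ± 0.03; 1.13e-15 and 1.64e-17). IL2RB was higher there in chimpanzee (3.56e-17). Moderated F-tests called 5076 probes in human and 3327 in chimpanzee (1876 and 1681 after median centring). Of the 2207 called in both (1088 for independent lists) 1779 (80.6%) were highest in the same region. The caudate was the highest region for 2318 probes in human and 1441 in chimpanzee, the frontal pole for 1735 and 1241, the hippocampus for 1023 and 645.

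Each region was then set against the mean of the other 2, a contrast added after the data were seen. Medium spiny neuron markers were higher in caudate, with 10 of 11 risen in human (median 1.27, adjusted p = 3.71e-11, 0.00478 with an estimated correlation) and 11 of 11 in chimpanzee (median 1.58, 1.64e-21, 1.07e-04 with an estimated correlation). The adenosine receptor ADORA2A was 18.5-fold higher there in human and at least 19.7-fold in chimpanzee, PPP1R1B 6.71-fold and 9.72-fold. Glutamatergic markers were lower in caudate, 8 of 10 in each species (medians −1.33 and −1.32, adjusted p = 1.14e-10 and 1.31e-12; 8.09e-04 and 1.07e-04 with an estimated correlation), SLC17A7 at least 36.5-fold and 34.0-fold, since it was above background on 0 of 6 human and 1 of 5 chimpanzee caudate arrays. Synaptic vesicle genes (9 and 8 of 11 fell; 0.00478 and 0.0127 with an estimated correlation), neurons in general (8 and 6 of 9 fell; 0.00478 and 0.0192) and cortical layer markers (7 and 6 of 9 fell, 1 rose in each; 0.0316 and 0.0108) were lower in caudate too. Oligodendrocyte markers rose in caudate (14 of 15 in human, adjusted p = 1.34e-06, and 9 in chimpanzee, 1.60e-04), MBP by 1.23 and 0.86, and lost the call with an estimated correlation (adjusted p = 0.265 and 0.507 with an estimated correlation). In frontal pole they fell (13 and 6 of 15, adjusted p = 3.80e-07 and 9.73e-07; 0.285 and 0.343 with an estimated correlation). The 3 hippocampal markers measured did not follow the hippocampus: in human they had a median of −0.39 there (0 higher, 1 lower, adjusted p = 0.211) and of 1.14 in caudate (2 higher, 0.0916), and in chimpanzee of 0.39 in hippocampus (0.464) and −0.61 in frontal pole (0.0168).

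**Figure D4:**
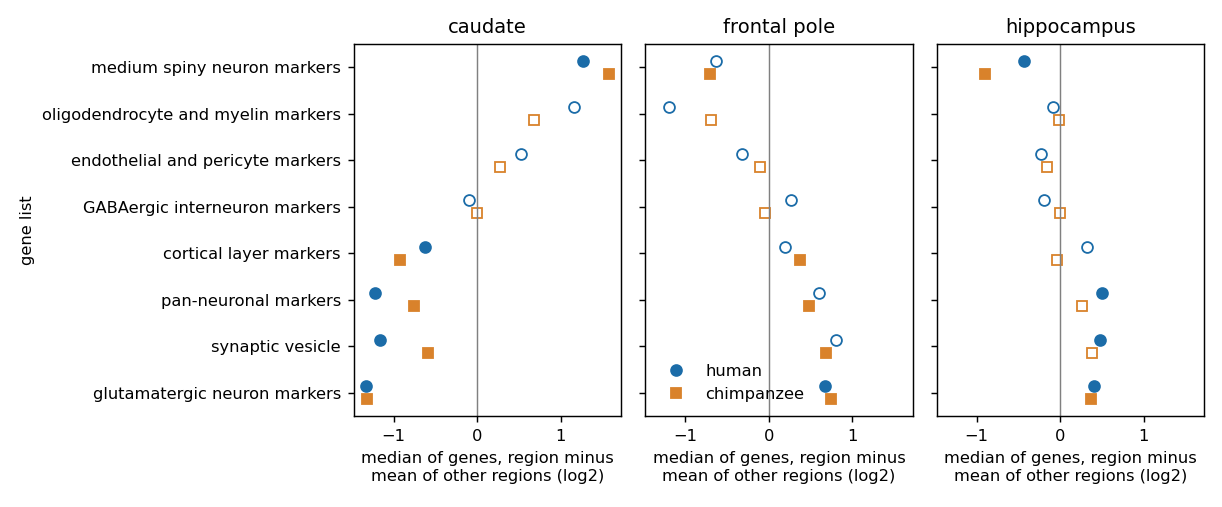
Median log2 difference of 8 gene lists in each region against the mean of the other 2 regions, human (circles) and chimpanzee (squares). Filled symbols had an adjusted p with an estimated correlation under 0.05; medium spiny neuron markers in caudate stood at 1.27 in human and 1.58 in chimpanzee.

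The species difference itself changed with the region for 342 probes by the moderated F-test. IL2RB was high in chimpanzee caudate (9.44 ± 0.62) and at 6.07 to 6.38 in the 5 other groups (adjusted p = 3.58e-11). LCN2 was high in chimpanzee frontal pole (8.42 ± 0.36) and hippocampus (8.65 ± 0.10) and not in chimpanzee caudate (6.39 ± 0.17) or in human (6.26 to 6.37; 4.58e-07), and NAALADL1, a homologue of the glutamate carboxypeptidases, stood at 8.08 ± 0.20 and 8.38 ± 0.10 in the same 2 groups against 7.04 ± 0.23 in chimpanzee caudate (2.04e-07). GALNT9 was brighter in human frontal pole (10.38 ± 0.18 against 9.02 ± 0.13) and hippocampus (10.43 ± 0.46 against 8.65 ± 0.21) and stood at 6.79 ± 0.33 and 6.67 ± 0.14 in caudate (3.08e-06; 0.0789 after median centring). The mitochondrial carrier UCP2 (8.92 ± 0.40 against 6.97 ± 0.21, 9.77e-06) and the lipid droplet protein CIDEC (7.79 ± 0.23 against 6.15 ± 0.12, 1.84e-05) were brighter in chimpanzee than human caudate, and CIDEC by less in frontal pole (6.73 ± 0.22 against 6.04 ± 0.07) and hippocampus (6.69 ± 0.15 against 5.98 ± 0.15). Median centring gave 63 probes, the arrays marked as outliers gave 83 when included, and leaving out 2 human frontal pole arrays, a choice made after the data were seen, gave 520.

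**Figure D5:**
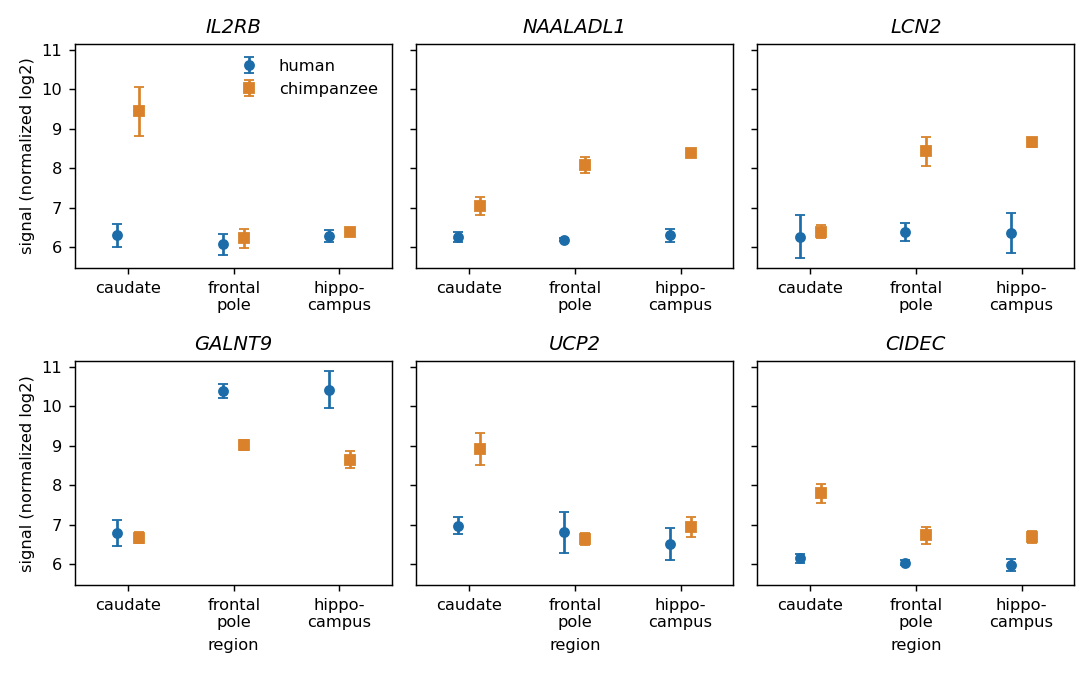
Log2 signal of IL2RB, NAALADL1, LCN2, GALNT9, UCP2 and CIDEC in each region of human and chimpanzee. Points are group means and error bars the SD over 4 to 6 arrays; IL2RB stood at 9.44 in chimpanzee caudate and 6.30 in human caudate.

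The last question was whether genes that differ between the 2 FOXP2 genotypes in cells also differ between the species. Without the line block no gene was called in cells, so 0 of the 3642 genes called in brain were shared (Fisher's exact test, p = 1, 6334 genes tested on both). With the block, chosen for this test after the data were seen, 39 of 85 cell genes were called in brain, fewer than the 48.9 of independent lists (odds ratio 0.62, Fisher's exact test, p = 0.0353), and 22 had the same direction (exact binomial test, p = 0.522). With value-table probes alone in brain the numbers were 32 against 41.9 (Fisher's exact test, p = 0.0374), with 19 in the same direction (exact binomial test, p = 0.377). The cell genes of this test rest on cultures taken as replicates: on line means with the block 0 probes were called. Without humanFOXP2 line 6 the blocked fit called 5. Opposite directions (cells, then the brain region of smallest p) were seen for the Wnt receptor ROR2 (dim in human brain), ZCCHC12 (0.42 and −2.27), RUNX1T1 (0.74 and −0.71), LINGO1 (0.47 and −1.07), SLIT1 (0.54 and −0.86) and SVIL (0.23 and −0.68). The same direction was seen for MGST1 (near background in cells, with 3 and 1 of 12 arrays above it, so that its direction there is uncertain), FAM43A (−0.52 and −0.97), the glutaredoxin GLRX (−0.41 and −0.75) and FAM167A (−0.33 and −0.73).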

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

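The tests of the probe classes in brain were chosen only after their results were seen, and so were the 5 sets of brain arrays, the counts with them as a block and the probes chosen without line 1 or 6. The other tests in this part were written before.

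The species differences leaned to higher in chimpanzee among probes that the value table keeps (23.9% of called caudate probes higher in human) and to higher in human among those it leaves out. One scale over both classes was tested as a cause: over the kept probes alone 45.4% of called caudate probes were higher in human, but normalizing each class alone centres its differences, so this outcome was set by the method. Weaker binding of chimpanzee RNA to the left-out probes was the other explanation; 69.8% of those called were higher in human, but this share had prompted it and so tests nothing. Both explanations and a difference of expression between the species, itself untested, cannot be told apart, because no outcome here was free to go against them.

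The species differences were also set against the sets of arrays that the value table treats alike, since sets and species overlap: set 1 held 3 human and 2 chimpanzee arrays and the other 4 sets held 1 species each. With the set as a block 95.6% of called caudate probes kept their direction. These probes had been called on the same arrays, which favours an unchanged direction. Set 1 alone compares the species within a set there, with 1 array of each. The share therefore does not decide whether the sets are the cause in caudate. In frontal pole (90.2%) and hippocampus (97.9%) no set holds both species, so these shares rest on effects of set and region that add up, and exclude nothing. The median size of the called differences went from 0.63 to 0.57 in caudate, 0.63 to 0.49 in frontal pole and 0.60 to 0.57 in hippocampus, while the SE grew 1.62, 1.87 and 1.72 times, so that 2522, 1101 and 2018 of the calls remained. A biological difference between the species remains a hypothesis beside the sets of arrays and beside probe mismatch, which was not tested.

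FOXP2 amount differs between the genotypes as well as its sequence, since humanFOXP2 lines held more transcript in lines 1 and 6 and less in line 7. If the amount were the cause of the differences between humanFOXP2 and chimpFOXP2, probes chosen on lines 1 and 6 would lose or turn their difference in line 7. Their median ratio in line 7 was −0.096 (489 probes, 35.2% in the same direction). Probes chosen without line 1 or line 6 gave −0.29 (178 probes, 33.7%) and −0.13 (132, 45.5%) in the line left out, where humanFOXP2 held more FOXP2, so the lines were unlike whichever was left out. Amount and sequence of FOXP2 cannot be told apart from differences between single lines, because there are 3 lines.

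Single arrays stood apart in 8 of 116 groups tested with Dixon's criterion, where chance alone gives 5.8. GSTT1 and HLA-DRB5 were left out of these tests, because their level in a person follows a common deletion or haplotype. The gap over the range was 0.875 for the median signal of the human frontal pole arrays. It was 0.936 and 0.883 for TM2D3 in chimpanzee frontal pole and hippocampus, 0.703 for ZNF91 in chimpanzee frontal pole, 0.712 for LCN2 in human hippocampus, 0.626 and 0.641 for NAALADL1 in human and chimpanzee hippocampus, and 0.633 for RPL36 in human hippocampus.

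By moderated F-tests, genotype differences changed with line number for 401 probes (humanFOXP2 vs control), 2596 (chimpFOXP2 vs control) and 2881 (humanFOXP2 vs chimpFOXP2). These tests took the cultures of a line as replicates, because lines of a given number were not replicated within a genotype. They therefore cannot tell a genotype effect that depends on line number from differences between single lines. The species difference changed with the region for 342 probes, among them IL2RB (adjusted p = 3.58e-11), NAALADL1 (2.04e-07), LCN2 (4.58e-07), GALNT9 (3.08e-06), UCP2 (9.77e-06) and CIDEC (1.84e-05).

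Other splits of the samples were fitted for each count. In brain 100 splits were drawn per comparison, the real one included. For caudate, frontal pole and hippocampus 1 split in each, the real one, called as many probes (6113, 5257 and 5876, against 4370, 1724 and 2590 at most in the others). For regions within human (5076 against 1428) and within chimpanzee (3327 against 235) it was 1 as well. No other drawn split reached the real count in these 5, which argues against chance alone. The draws do not part species from the sets of arrays. For species by region 3 splits called as many (342, highest other 739). That share does not exclude chance, because the draws shuffle regions within a species and so break the differences between regions as well. The draws also mix regions across individuals, and the 739 calls of a split point to a structure of the samples. In cells the 10 splits of 6 lines are too few for such a share: 5, 8 and 10 splits called as many as the real 1, 1 and 0 probes, with 292, 749 and 885 at most. Those high counts came from splits that kept lines of the same number together and point to a structure of the samples by line number. The 4 splits that part all pairs are too few for a share as well. With the block 1, 3 and 4 of them, the real one included, called as many as the real 8, 195 and 162. The others called 0, 4 and 1, then 559, 85 and 525, then 258, 288 and 286. For humanFOXP2 vs chimpFOXP2 the real genotypes thus called the fewest probes. For chimpFOXP2 vs control they called fewer than the splits with 559 and 525.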

How the results depend on the processing

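Tests on single line numbers, on the blocked fit under other settings, with the sets of the value table as a block, without 2 human frontal pole arrays, of the overlap and lists with the line block, and of the lists on line means with the block or on value-table probes alone were chosen only after the results were seen; the other alternatives were planned. Blocks for the beadchip and probes that match chimpanzee sequence were not run. Among the named genes no difference that was called, in the main fit or in the other setting, turned its sign. Over all probes some called differences did. With the sets of the value table as a block 95.6%, 90.2% and 97.9% of called probes kept their direction in caudate, frontal pole and hippocampus. Differences that were not called turned too, such as FOXP2 between humanFOXP2 and chimpFOXP2 (0.55, and −0.25 in line 7 alone). LGALS1 between chimpFOXP2 and control went from 0.15 to −0.06 with line 7 left out. Counts below are in the order humanFOXP2 vs control, chimpFOXP2 vs control, humanFOXP2 vs chimpFOXP2 for cells and caudate, frontal pole, hippocampus for brain; the cause of a change was not tested unless a smaller number of arrays or probes gives it. Signal over background limits the dim probes most: 32.0% to 59.5% of probes lay above background on the arrays used.

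Without the block the counts in cells were 1, 1 and 0. The line block gave 8, 195 and 162, line and culture together 6, 92 and 43, and all 36 arrays taken as independent 2, 32 and 3. Line means called 0 probes for chimpFOXP2 vs control, and line means with the block 0 and 0 against control. The value table gave 7 and no filter 3 for chimpFOXP2 vs control. Single lines, with their cultures taken as replicates, gave 39, 1504 and 1674 (line 1), 138, 1714 and 2390 (line 6) and 316, 533 and 18 (line 7). These counts include differences between single lines that need not come from the genotype. Leaving out 1 line of a genotype gave 1 to 2, 1 to 26 and 0 to 26 probes, the highest without humanFOXP2 line 6, chimpFOXP2 line 1 and chimpFOXP2 line 7.

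From the blocked 8, 195 and 162, the strict filter gave 5 for humanFOXP2 vs control, and fits of the 2 genotypes alone gave 230 for humanFOXP2 vs control and 70 for humanFOXP2 vs chimpFOXP2. Leaving line 1 out of every genotype gave 16 and 392 in the first 2 comparisons, line 6 gave 42, 123 and 40, and line 7 gave 5, 649 and 676. Leaving out 1 line of 1 genotype gave 4 to 46, 63 to 1007 and 5 to 1189.

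In brain, value-table probes normalized alone gave 2954, 2270 and 2745 calls from 6113, 5257 and 5876, partly because fewer probes were tested, and the sets as a block 2906, 1306 and 2210. The title numbers do not pair the brain arrays across species: arrays of 1 number correlated at r = −0.13 to 0.05 (caudate), −0.10 to 0.13 (frontal pole) and −0.12 to 0.22 (hippocampus), and with them as a block the frontal pole alone gave 3154. Median centring gave 1876 and 1681 for regions within human and chimpanzee, from 5076 and 3327, and including the arrays marked as outliers 3049 and 1724. Species by region, 342 probes, went to 63 with median centring, 83 with the outlier arrays, 208 without a filter, 201 on the value table, 101 without the random block and 520 without 2 human frontal pole arrays; leaving out 1 array gave 216 to 443. Leaving out any array moved each other brain count by less than 1.5 times. The overlap went from 0 to 39 with the line block.

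Of the lists without the block, 4, 8 and 7 were called. With an estimated correlation 2 and 3 were called for humanFOXP2 vs control and humanFOXP2 vs chimpFOXP2, on line means 2 and 4, and on line means with the block 0, 5 and 4. From the blocked 3, 8 and 7, line means gave 0, 5 and 4, and the estimated correlation gave 3 for humanFOXP2 vs chimpFOXP2. Of the brain lists 1, 0 and 2 were called. With an estimated correlation, and on value-table probes, caudate and hippocampus gave 0 and 0, median centring gave 4 in caudate, and the sets as a block 4, 1 and 4.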

Other observations

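The genes of this part were chosen only after their values were seen, and so were the tests on them.

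Tyrosine hydroxylase, TH, the first enzyme of dopamine synthesis, was measured by 2 probes in brain. In human caudate (n = 6) they stood at 7.97 ± 0.23 and 7.66 ± 0.19, above background on 6 of 6 arrays, and in chimpanzee caudate (n = 5) at 6.31 ± 0.23 and 6.22 ± 0.33, above background on 1 of 5. TH was at least 2.67-fold (SE 0.16 on the log2 scale, adjusted p = 4.77e-10) and 2.14-fold (SE 0.15, adjusted p = 1.03e-09) higher in human caudate, and the call held in all 33 fits with an array left out and in all 13 other settings. The frontal pole showed no call (adjusted p = 0.149 and 0.518) and the hippocampus a call for 1 probe (0.291 and 0.0161), above background there on 2 of 6 human and 1 of 6 chimpanzee arrays and not called with the sets of the value table as a block (0.687). The species difference of TH changed with the region (adjusted p = 2.13e-05 and 1.01e-04), which was lost when arrays marked as outliers were included (0.119 and 0.217). DDC, the next enzyme of the pathway, lay near background: in caudate it was above it on 4 of 6 human and 0 of 5 chimpanzee arrays (6.94 ± 0.42 against 6.12 ± 0.17, adjusted p = 4.09e-04), and the call was lost with the sets of the value table as a block (0.483).

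The list of GABAergic interneuron markers was not called (adjusted p = 0.0666 in caudate, 0.992 in frontal pole and 0.196 in hippocampus), but of its 12 genes 7 were called lower in human in caudate and 7 in hippocampus, none higher, and in frontal pole 2 lower and 1 higher. The 3 given here were chosen from them. Among the 9941 tested probes that the value table keeps, 2706 were called lower and 848 higher in human caudate. In hippocampus these were 2621 and 791, and in frontal pole 2395 and 618. GAD2 was brighter in caudate than in the other regions in both species. Whether these genes stand for interneurons in caudate was not tested. In caudate the neuropeptide VIP was 2.68-fold higher in chimpanzee (8.62 ± 0.38 against 7.25 ± 0.43, SE 0.20, adjusted p = 7.88e-07) and GAD2, which makes GABA, 2.30-fold (11.67 ± 0.14 against 10.44 ± 0.49, SE 0.21, 2.97e-05). In hippocampus somatostatin, SST, was 3.02-fold higher in chimpanzee (11.57 ± 0.23 against 9.98 ± 1.14, SE 0.33, adjusted p = 2.58e-04) and GAD2 1.76-fold (0.00183). The GAD2 call in hippocampus was kept in 11 of 13 other settings (adjusted p up to 0.0773). The calls of VIP and GAD2 in caudate and of SST in hippocampus held in all settings. No call was made for SST in caudate (0.0812, with the same outcome in 9 of 13 other settings), for VIP in hippocampus (0.516), or in frontal pole for VIP (0.342), GAD2 (0.128) or SST (0.870). The species difference changed with the region for VIP (adjusted p = 0.00402), which was lost in 2 of 11 settings (0.795 with the arrays marked as outliers), and passed no such test for GAD2 (0.282) or SST (0.120).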
